A study of Mus musculus with 12 samples.

How the data were processed

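The data are liver transcriptomes of 12 obese C57BL/6 mice, 6 with a scaffold pellet and 6 with a 4-HPAA pellet for 6 weeks. Per the labels' protocols, RNA was purified with RNeasy columns, checked on a Bioanalyzer, made into directional TruSeq mRNA libraries and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name FastQC 0.11.9, cutadapt, STAR, HTSeq, DESeq2 1.28.1 and edgeR, and the mouse build GRCm38. The role and order of these tools, the versions of the others and the annotation release are not given in the sources used here.

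The deposited table holds 13267 genes, each under 1 Ensembl transcript ID, in 12 libraries, and no column of other samples. Its values are whole numbers but not raw counts, so they were handled as a score, that is, the authors' read counts scaled by 1 factor per library and rounded. This was read from the deposited values themselves: some low whole numbers are missing and others are over-represented at regular spacing, which fits factors between 0.849 and 1.13, and median-of-ratio size factors of the columns all lie between 1.00 and 1.01. The smallest value in the table is 2 and it holds 0 genes of the mitochondrial chromosome, so a gene without reads in some library is not in it, and a gene switched fully on or off cannot be seen. Whether the counting used strand is not given in the sources used here. IDs were matched to GENCODE M21 (Ensembl 96, GRCm38), which named 13203 of them, 12764 protein coding, while 64 stayed unnamed.

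The depth of a library was taken as the total of its values divided by its inferred factor, 22388558 to 26924668 reads. At the smallest values tested, near 10, counting error alone is large, and differences there are less certain. The test planned before the data were examined was for raw counts (edgeR quasi-likelihood), and it was not used because the values are scaled. In its place, limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust settings) was run on log2(value + 1) for the 12720 genes with a value of at least 10 in at least 6 libraries. A fold change is thus on the log2(value + 1) scale, which understates the change of low genes, and a positive value means higher in 4-HPAA. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. No scaling was added, since the authors had scaled the libraries, and no covariate was used, since the labels name no batch. Limits of the replicates' origin are stated with the results.

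Of 39 gene lists written before the data were examined, 36 had at least 5 tested genes. They cover lipid, glucose, detoxification and stress pathways, matrix, clock and zonation genes, and markers of other cell types. Each list was tested against all other genes with limma camera at the preset correlation of 0.01, and again with an estimated correlation. Fry and exact permutation of the mean log2 value per mouse tested each list against no change, without comparison with other genes. Genes are named by a rule also fixed in advance. It takes the 8 largest increases and decreases among genes that pass with a mean of at least 1 CPM (the value per library total, scaled), filled up with the smallest p where fewer pass, the 12 metabolic genes chosen in advance, and up to 4 members of smallest p for each list described. Predicted genes were left out of the first part. Not every gene the rule takes is described. Saa1, Saa2 and Carmil1 were named after their values were seen.

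On simulated values with 200 changed genes at the spread of the real libraries (12731 genes, 6 against 6), limma recovered 89% of genes changed 2-fold and 98% of those changed 4-fold, with 3.61% false calls and 0 wrong signs. At low spread (12764 genes) it recovered 99% and 100%. In both runs genes were drawn independently, without a GC trend or an outlying library, and genes of low mean were left unchanged. These rates need not hold for the real libraries, where genes vary together. Of the 30 pairs of libraries within a group, none differed by as little as sampling noise, with a chi-square per gene of 18.04 to 115.28. Alternatives tried were other scalings, filters, pseudocounts and tests, sample weights, a replicate block, removal of GC trends (lowess, span 0.3, on the mean GC content of a gene's transcripts) and each library left out. The alternatives that need raw counts, a DESeq2 test and svaseq, were not used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.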

Results

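Liver messenger RNA was measured in 12 C57BL/6 mice that had become obese on a high-fat diet, with fat-laden livers (steatosis). In 6 mice a scaffold pellet was placed under the skin as control, and in the other 6 the pellet carried 4-hydroxyphenylacetic acid (4-HPAA), a small phenolic acid that gut bacteria form from dietary polyphenols. Livers were taken after 6 weeks. The design holds 1 comparison, 4-HPAA against scaffold control, and asks how the liver transcriptome of steatotic mice differs with the compound. The labels number the samples of each group from 1 to 6 and say no more of their origin, so p-values measure the spread between these samples, each taken as 1 mouse. The deposited values are normalised read counts for 13267 genes. They summed to between 22869813 and 25255447 per library, and the reads behind them were estimated at 22388558 to 26924668. Albumin alone took 7.59 to 8.72% of the total in control libraries and 4.98 to 7.58% in 4-HPAA libraries.

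Genes of the acute phase response were higher in 4-HPAA livers, and genes of lipid droplets, fatty acid metabolism, cholesterol synthesis and the extracellular matrix were lower, each as a list. The median log2 difference (4-HPAA minus control) was 0.55 over 34 acute phase genes, −0.57 over 31 matrix genes and −0.25 over 25 genes of triglyceride synthesis and lipid droplets. In all, 18 of 36 gene lists passed an adjusted p of 0.05 in limma's camera test, 6 higher and 12 lower. With an estimated correlation between the genes of a list, 0 of the 36 lists passed, the smallest adjusted p being 0.509. No single gene passed: of 12720 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05 and 4 had one under 0.1. At an unadjusted p under 0.05 there were 1886 genes, 924 higher and 962 lower in 4-HPAA, where chance alone gives 636 on average. Of 100 splits of the 12 livers into 6 and 6, the real one included, 7 gave as many genes, so chance cannot be excluded. For the 18 lists of the camera test, 9 of these splits gave as many, so chance cannot be excluded there either. With sample quality weights (limma voom) 7 genes passed, and with a replicate block (limma) 11. The count of genes was 193 without 4-HPAA replicate 4, 5 without control replicate 1 and 0 without 4-HPAA replicate 3, the library that stood apart from all others, and the count of lists without that library was 19. Limma's fry test of change in either direction, added after the data were seen, called 14 lists, but 1 without 4-HPAA replicate 2 and 21 without 4-HPAA replicate 4 or 6.

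Along the first principal component of the 12 livers, which held 31.5% of the variance, 4-HPAA mice lay apart from controls (exact permutation test, two-sided, p = 0.0108). The scores of 4-HPAA replicates 4 and 6, at −10.94 and −1.15, lay within the control range of −31.52 to 2.02. Depth also differed along this component. 4-HPAA replicates 1, 2 and 5, at its high end, had the fewest estimated reads (22388558, 23359064 and 23766597). Control replicates 4 and 5, at its low end, had 25839715 and 26924668. 4-HPAA replicate 3 departed from this, with 25917971 reads at a score of 12.22. Whether depth plays a part in this component was not tested. The second component, with 20.6% of the variance, set 4-HPAA replicate 3 apart at −56.45 from all other livers, which lay between −7.52 and 17.03.

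**Figure D1:**
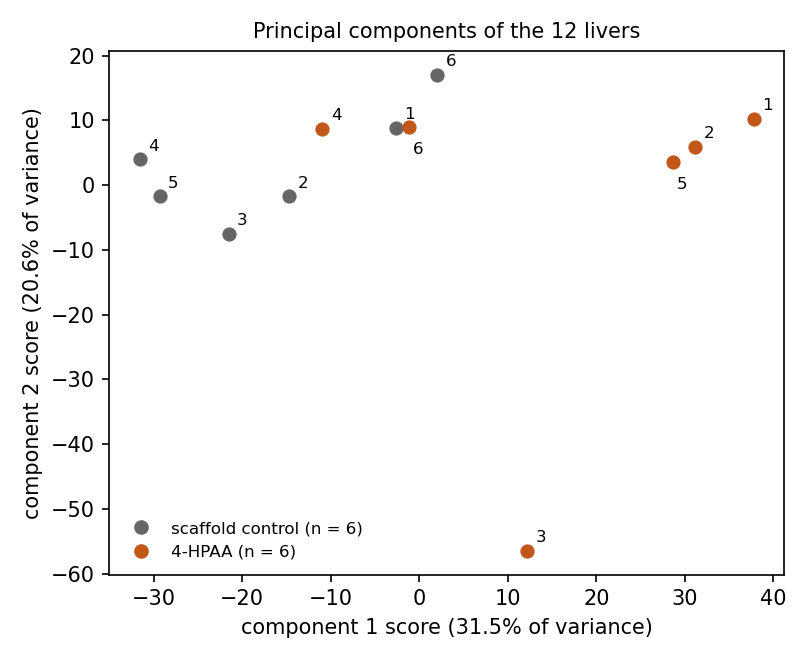
Scores of the 12 livers on the first component (horizontal axis, 31.5% of variance) and the second component (vertical axis, 20.6% of variance) of log2(value + 1), with 1 point per mouse, numbered by replicate and coloured by group. Of the 4-HPAA mice, replicates 1, 2 and 5 lie at 28.65 or above on the first component, replicates 4 and 6 lie among the controls, and replicate 3 lies at −56.45 on the second.

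Genes that build and coat lipid droplets were lower in 4-HPAA livers. The list of triglyceride synthesis and lipid droplets fell, with 20 of its 25 measured genes at negative differences (limma camera, adjusted p = 2.41e-05; adjusted p = 0.509 with an estimated correlation). None of its genes passed over all genes tested, and 7 passed when adjusted over the list alone, all lower. Fitm2, which partitions triglyceride into droplets, averaged 2652 ± 265 in controls and 1989.8 ± 149 with 4-HPAA (SD, n = 6 each), a log2 difference of −0.41 ± 0.08 (SE). Hsd17b13, a protein of the droplet surface, differed by −0.51 ± 0.10, and G0s2, an inhibitor of triglyceride lipase, by −0.76 ± 0.24. Pparg, a transcription factor that drives fat storage, averaged 456 ± 121 and 282 ± 66.3 (SD, n = 6 each), a difference of −0.69 ± 0.19. Among the other genes chosen in advance, the droplet protein Cidec differed by −1.76 ± 0.58 and the droplet coat protein Plin2 by −0.50 ± 0.22, and neither passed over all genes (limma, adjusted p = 0.207 and 0.307). Adipose tissue markers moved the same way: 9 genes, of which 6 also belong to another list, 3 of them to the droplet list, had a median of −0.54 and fell as a list (limma camera, adjusted p = 0.000685; adjusted p = 0.509 with an estimated correlation). Of these markers, 4 passed when adjusted over the list alone and none over all genes: Pparg, Cfd (−2.65 ± 0.73), Cidea (−2.60 ± 0.87) and Fabp4 (−0.54 ± 0.19).

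**Figure D2:**
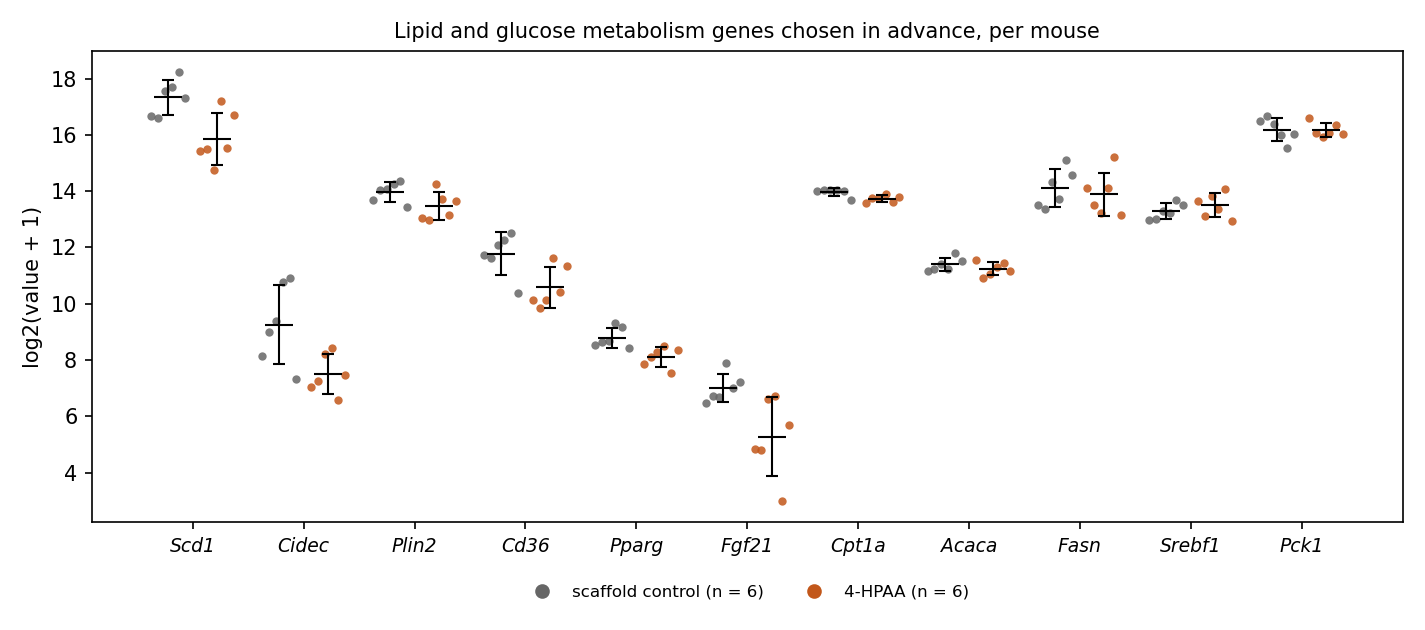
Log2(value + 1) of metabolic genes chosen in advance (vertical axis) for each gene and group (horizontal axis), with 1 point per mouse and the mean ± SD of 6 mice as the black bar. Scd1, Cidec, Cd36 and Fgf21 show log2 differences of −1.49, −1.76, −1.19 and −1.72, with 4-HPAA mice overlapping control mice, while Pck1 shows −0.01.

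Genes of fatty acid synthesis and modification were also lower as a list. Of the 22 genes of de novo lipogenesis, 15 had negative differences, with a median of −0.31 (limma camera, adjusted p = 0.00393; adjusted p = 0.539 with an estimated correlation). None passed over all genes, while 8 lower and 2 higher genes passed when adjusted over the list alone. Among the members with the smallest p were enzymes that desaturate or elongate fatty acids: Scd1, the stearoyl-CoA desaturase, averaged 179030 ± 76660 in controls and 70462 ± 47620 with 4-HPAA (SD, n = 6 each), a log2 difference of −1.49 ± 0.40, Elovl5 differed by −1.09 ± 0.26 and Fads1 by −0.52 ± 0.14. Mlxipl, the carbohydrate-responsive transcription factor, was at 0.43 ± 0.13, on the higher side. Of the other genes chosen in advance, Fasn was at −0.22 ± 0.37, Acaca at −0.15 ± 0.13 and Srebf1 at 0.21 ± 0.18 (limma, unadjusted p = 0.566, 0.261 and 0.281). The sign of Fasn turned with sample weights, to 0.09 with quality weights and 0.08 with array weights. The call of this list was lost without control replicate 5 (limma camera, adjusted p = 0.0507) and with array weights (adjusted p = 0.107), and its adjusted p ranged from 0.000223 to 0.539 over 26 alternatives.

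Fatty acid oxidation and uptake genes fell alongside. The list of oxidation genes and targets of PPAR-alpha, the nuclear receptor for fatty acids, had 33 of 37 genes at negative differences and a median of −0.21 (limma camera, adjusted p = 2.89e-06; adjusted p = 0.539 with an estimated correlation). None of them passed over all genes or when adjusted over the list alone, although 16 had an unadjusted p under 0.05, all lower. Fgf21, a fasting hormone made by the liver, differed by −1.72 ± 0.54, Pdk4 by −0.84 ± 0.29, Acot4 by −1.05 ± 0.35 and Vnn1 by −0.79 ± 0.27, while Cpt1a, which carries fatty acids into mitochondria, differed by −0.23 ± 0.08. The list of fatty acid uptake and lipoprotein handling fell as well, with 18 of 27 genes negative (limma camera, adjusted p = 0.00288; adjusted p = 0.509 with an estimated correlation), and none of its genes passed over all genes or when adjusted over the list alone. Its leading genes were Fabp2 (−0.63 ± 0.18), the fatty acid transporter Cd36 (−1.19 ± 0.38), Apoa4 (−0.99 ± 0.32) and Fabp1 (−0.41 ± 0.14). Nuclear-encoded genes of oxidative phosphorylation did not pass (62 genes, limma camera, adjusted p = 0.13), but passed as lower without 4-HPAA replicate 3 at the preset correlation (limma camera, adjusted p = 8.06e-05, within a range of 5.19e-05 to 0.977 over 26 alternatives). The list had an adjusted p = 0.911 with an estimated correlation over all 12 libraries, and 0.64 without replicate 3 (limma camera).

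Cholesterol synthesis genes were lower too, with 21 of 24 at negative differences and a median of −0.27 (limma camera, adjusted p = 8.09e-05; adjusted p = 0.539 with an estimated correlation). Of these, 2 passed when adjusted over the list alone, Acat2 (−0.57 ± 0.14) and Hmgcs1 (−0.83 ± 0.23), and none over all genes. The list of genes driven by NRF2, the regulator of antioxidant defence, fell (27 genes, limma camera, adjusted p = 0.00347; adjusted p = 0.539 with an estimated correlation), yet the 1 gene that passed when adjusted over the list alone, Osgin1, was higher at 0.88 ± 0.21.

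Acute phase genes, which hepatocytes transcribe in response to inflammatory cytokines, were higher in 4-HPAA livers. Of 34 genes, 29 had positive differences (limma camera, adjusted p = 2.98e-12; adjusted p = 0.509 with an estimated correlation). None passed over all genes, while 22 higher and 1 lower gene passed when adjusted over the list alone. The score of the list, its mean log2 value per mouse, was 0.72 above the control mean with 4-HPAA, and all 6 4-HPAA mice lay above that mean (exact permutation test, two-sided, p = 0.00216, the smallest possible, and 0.0779 after Benjamini-Hochberg adjustment over 36 lists). Serpina3k, a serine protease inhibitor, differed by 0.75 ± 0.19, Orm1, an orosomucoid, by 1.05 ± 0.26, Itih4 by 0.57 ± 0.15 and Fgl1 by 1.27 ± 0.34. Serum amyloid genes, named after their values were seen, varied widely between 4-HPAA mice: Saa1 averaged 1976.7 ± 538 in controls and lay at 37622, 63934, 12759 and 27065 in 4-HPAA replicates 1, 2, 3 and 5, but at 2844 and 2196 in replicates 4 and 6. Saa1 and Saa2 are close copies, so reads could be divided between them by the authors' counting. The Kupffer cell and macrophage list did not pass, with a median of −0.16 over 25 genes (limma camera, adjusted p = 0.117). It passed as lower without control replicate 1, 2 or 3 or 4-HPAA replicate 5 (adjusted p = 0.00497, 0.0137, 0.0085 and 0.033, limma camera), and with 1 library left out its median ranged from −0.29 to 0.02 and its adjusted p from 0.00497 to 0.747. With an estimated correlation it had an adjusted p = 0.873 over all libraries and 0.614 to 0.977 with 1 left out (limma camera). Control mice spread widely in this list, with an SD of the score of 0.61 against 0.16 in 4-HPAA mice. Control replicates 1, 2 and 3 scored −0.657, −0.451 and −0.527 from the control mean, and replicates 4, 5 and 6 scored 0.492, 0.415 and 0.729. The control scores of T, NK and B cell markers and of inflammatory cytokines were likewise negative in replicates 1 to 3 and positive in 4 to 6. The labels name no grouping of these mice, and the cause was not tested. Its leading members were mixed, with Itgax at −1.02 ± 0.34, Cx3cr1 at −1.18 ± 0.43, Ccr2 at −0.80 ± 0.36 and Mpeg1 at 0.43 ± 0.21. Inflammatory cytokines and NF-kB targets did not pass either (24 genes, limma camera, adjusted p = 0.988), with a median of 0.01 and a mean of −0.06.

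**Figure D3:**
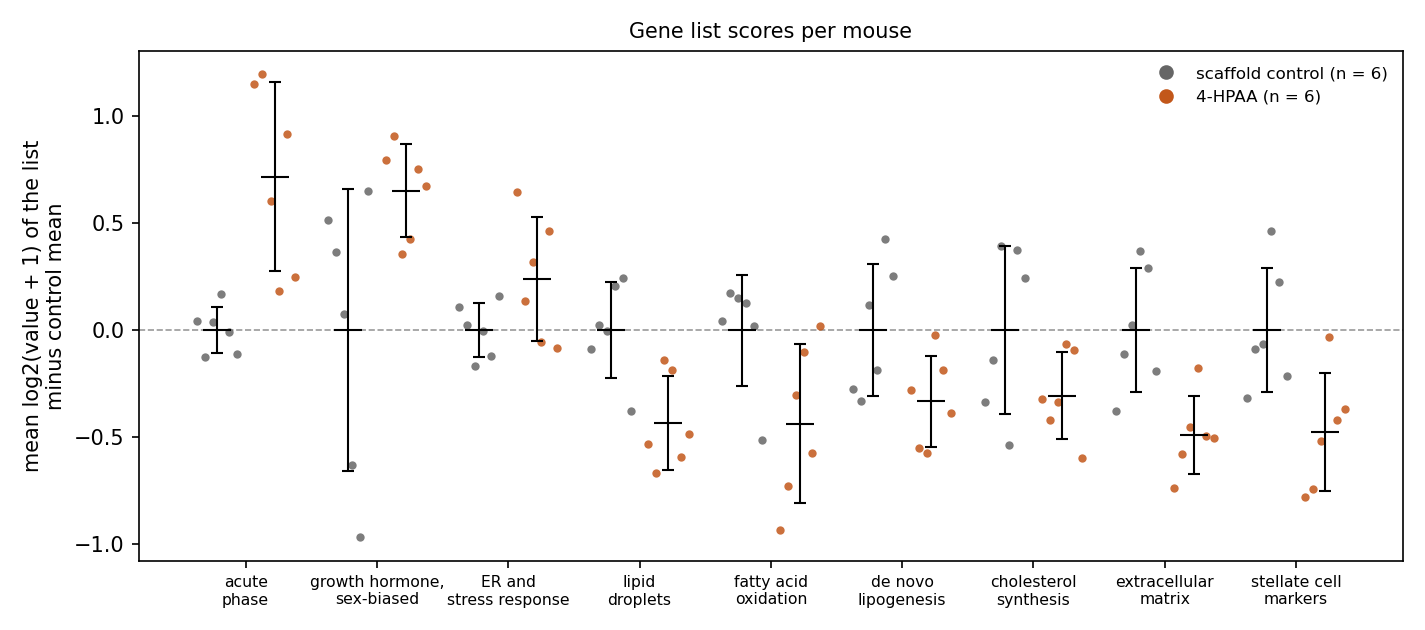
Mean log2(value + 1) of the genes in each of 9 lists, minus the control mean (vertical axis), for each list and group (horizontal axis), with 1 point per mouse and the mean ± SD of 6 mice as the black bar. For acute phase genes the 6 4-HPAA mice lie between 0.18 and 1.20, all above the highest control at 0.17, while in the other lists the groups overlap.

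Chaperone genes were higher as lists. The endoplasmic reticulum and integrated stress response list rose, with 23 of 30 genes positive and a median of 0.26 (limma camera, adjusted p = 0.000336; adjusted p = 0.509 with an estimated correlation). The lumenal chaperones Dnajb11 (0.52 ± 0.15), Calr (0.45 ± 0.13) and Sdf2l1 (1.00 ± 0.34) led it, while its member Fgf21 was on the lower side. The heat shock list rose, with a median of 0.23 over 23 genes (limma camera, adjusted p = 0.000973; adjusted p = 0.555 with an estimated correlation), led by the HSP90 partners Fkbp4 (0.27 ± 0.09), Stip1 (0.41 ± 0.13) and Ahsa1 (0.22 ± 0.08). No gene of either list passed over all genes or when adjusted over the list alone, and in each list 4 of 6 4-HPAA mice lay above the control mean.

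Growth hormone-dependent and sex-biased liver genes rose as a list, with 22 of 31 genes positive and a median of 0.62 (limma camera, adjusted p = 0.000111; adjusted p = 0.509 with an estimated correlation). None passed over all genes, and 8 higher and 1 lower gene passed when adjusted over the list alone. The complement genes C6 (1.11 ± 0.30) and C8b (1.01 ± 0.30), the oxysterol hydroxylase Cyp7b1 (1.38 ± 0.41) and the major urinary protein gene Mup17 (2.77 ± 0.79) had the smallest p. Mup17 belongs to a cluster of near-identical genes, so its own level is uncertain. Control mice varied widely in this list, with an SD of the score of 0.66 against 0.22 in 4-HPAA mice. Hepatocyte markers rose slightly, with a median of 0.06 over 22 genes (limma camera, adjusted p = 0.0362; adjusted p = 0.539 with an estimated correlation). Of these, 3 higher genes, among them Cyp2f2 (0.35 ± 0.08) and Ambp (0.36 ± 0.08), and 1 lower, albumin (Alb, −0.38 ± 0.10), passed when adjusted over the list alone, and none over all genes. Urea cycle and amino acid catabolism genes rose, with a median of 0.07 over 37 genes (limma camera, adjusted p = 0.0306; adjusted p = 0.509 with an estimated correlation). Ass1 was at 0.21 ± 0.07 and Cps1 at 0.36 ± 0.17, and no member passed over all genes or when adjusted over the list alone. The hepatocyte call held in 12 and the urea cycle call in 15 of 26 alternatives.

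Collagens and other extracellular matrix genes were lower in 4-HPAA livers. Of 31 genes, 29 had negative differences (limma camera, adjusted p = 2.53e-11; adjusted p = 0.509 with an estimated correlation), and 18 lower and 1 higher gene passed when adjusted over the list alone, against 0 over all genes. The type VI collagen genes Col6a3 (−0.87 ± 0.15), Col6a2 (−0.83 ± 0.19) and Col6a1 (−0.68 ± 0.15) led the list with Col3a1, of type III collagen, which averaged 1013.2 ± 379 in controls and 487 ± 130 with 4-HPAA (SD, n = 6 each). Markers of stellate cells and fibroblasts, the matrix-producing cells, fell in the same livers: all 20 had negative differences, with a median of −0.42 (limma camera, adjusted p = 8.13e-08; adjusted p = 0.509 with an estimated correlation). Of these, 9 passed when adjusted over the list alone and none over all genes, and 7 of the 20 also belong to the matrix list. Reln, made by stellate cells, differed by −0.65 ± 0.14. Endothelial markers fell with a median of −0.17 over 21 genes (limma camera, adjusted p = 0.00357; adjusted p = 0.599 with an estimated correlation), with Pecam1 at −0.31 ± 0.12, and cholangiocyte and progenitor markers with a median of −0.33 over 15 genes (adjusted p = 0.0168; adjusted p = 0.509 with an estimated correlation), with Krt23 at −2.02 ± 0.69. Cell cycle genes fell, with a median of −0.18 over 26 genes (limma camera, adjusted p = 0.00707; adjusted p = 0.539 with an estimated correlation), with Ccnd1 at −0.80 ± 0.23. No member of these last 3 lists passed over all genes or when adjusted over the list alone. The cholangiocyte call was lost with the stricter filter, at a median of 0.06 over 6 genes (limma camera, adjusted p = 0.845), and without control replicate 3 (0.0804) or 4-HPAA replicate 6 (0.0613), and ranged from 0.00439 to 0.845 over 26 alternatives. The cell cycle call was lost without control replicate 5 (limma camera, adjusted p = 0.0649) or 4-HPAA replicate 6 (0.0613) and with array weights (0.112), and ranged from 0.000201 to 0.539 over 25 alternatives.

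Drug-metabolising and conjugating enzymes differed in both directions. In the list of xenobiotic cytochromes P450, 5 genes were on the higher and 4 on the lower side among those that passed when adjusted over the list alone, none passed over all genes, and the list changed in either direction (33 genes, limma fry, adjusted p = 0.0113) but not on balance (limma camera, adjusted p = 0.803). The either-direction call was lost without control replicate 4 or 5 or 4-HPAA replicate 2 (limma fry, adjusted p = 0.0562, 0.0514 and 0.0697, within a range of 0.00112 to 0.0697 with 1 library left out). Cyp3a11 averaged 18486 ± 5149 in controls and 7412.2 ± 3637 with 4-HPAA (SD, n = 6 each), a difference of −1.41 ± 0.28, whereas Cyp1a2 was at 0.76 ± 0.18 and Cyp2d40 at 0.53 ± 0.13. Phase II enzymes passed the same test over all libraries (46 genes, limma fry, adjusted p = 0.0229; limma camera, adjusted p = 0.182), but in only 5 of 12 fits with 1 library left out (limma fry, adjusted p 0.00159 to 0.103). With the stricter filter the list passed as lower (42 genes, limma camera, adjusted p = 0.0164, within a range of 0.0164 to 0.805 over 26 alternatives), and it had an adjusted p = 0.773 with an estimated correlation over all genes tested. Of their genes, 4 higher and 5 lower passed when adjusted over the list alone and none over all genes. Gstp1, a glutathione transferase, averaged 12270 ± 2979 in controls and 33577 ± 12120 with 4-HPAA, with all 6 4-HPAA mice above all 6 controls, and Ugt2b38 was at 2.52 ± 0.66 while Ugt1a5 averaged 571 in controls and 276.5 with 4-HPAA. The Ugt1a genes share exons and the Ugt2b genes are close copies, so single members are uncertain.

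Because no gene passed, genes with the smallest p in each direction are given as not passing. The smallest adjusted p was 0.0809 (limma, Benjamini-Hochberg), the value of Pltp, Obp2a and Ltbp4 among others. Pltp (ENSMUSG00000017754, GRCm38 chromosome 2, 164839518 to 164857711), the phospholipid transfer protein of plasma lipoproteins, averaged 1075.2 ± 387 in controls and 291 ± 101 with 4-HPAA (SD, n = 6 each), a difference of −1.84 ± 0.28. Obp2a (ENSMUSG00000062061, chromosome 2, 25700043 to 25703326), an odorant-binding lipocalin, averaged 10 ± 7.18 and 43.5 ± 14.1, close to the lowest values tested. The matrix protein gene Ltbp4 (ENSMUSG00000040488, chromosome 7, 27305136 to 27337692) differed by −0.66 ± 0.11. Also lower were the intermediate filament gene Vim (−0.82 ± 0.15), Mcam (−0.63 ± 0.12), Anxa1 (−0.89 ± 0.17), Adgrd1 (−1.18 ± 0.23) and Col6a3. Besides Gstp1 and Obp2a, the higher side held Tmie (0.55 ± 0.10), the steroid 5-alpha reductase Srd5a1 (0.54 ± 0.10), Nnmt (0.85 ± 0.17), Myom3 (1.61 ± 0.32), Car14 (0.67 ± 0.13) and Sh3pxd2a (0.55 ± 0.11). With quality weights the genes that passed included Ltbp4, Obp2a, Tmie, Col6a3, Fitm2 and Carmil1, the last chosen after its values were seen (0.93 ± 0.15 in that fit; limma voom, adjusted p = 0.04). With the replicate block 11 genes passed, 1 higher and 10 lower, among them Pltp, Col6a3, Vim and Anxa1 (limma, adjusted p = 0.0497 each).

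Several lists chosen for pathways that could respond to the compound did not pass. Genes of the energy sensor AMPK and of mTORC1 signalling had a mean difference of −0.03 over 36 genes (limma camera, adjusted p = 0.878), and the direction of the camera test turned in 5 of 26 alternatives, in 3 of them with a median above 0. Gluconeogenesis, glycogen and insulin response genes did not pass (limma camera, adjusted p = 0.858), with Pck1 at −0.01 ± 0.17, and their median and mean were negative where the camera test gave a higher direction. Tyrosine and phenylalanine catabolism, the pathway of amino acids related to 4-HPAA, had an adjusted p of 0.644 (limma camera), and bile acid and sterol handling one of 0.741.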

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

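The tests of explanations in this part were chosen only after the result was seen. Of 294 groups of 6 values checked, single genes as deposited values, 24 held a sample far from its group by the Dixon gap criterion. For normally distributed values chance gives about 14.7. A check of all genes tested used log2 values, so its scale differs. There 4-HPAA replicate 3 was far from its group in 1432 genes (11.26%) and 4-HPAA replicate 4 in 50 (0.39%). Of the 24, 8 were high values of 4-HPAA replicate 4. Its values were 483 for Pltp (others 190 to 298), 412 for Vim (others 240 to 294), 35 for Top2a (others 12 to 19), 2345 for Acat2 (others 1574 to 1750), 58 for Ccr2 (others 11 to 26), 245 for Fabp4 (others 130 to 173) and 441 for Ugt1a5 (others 210 to 266), and its inflammatory cytokine score was 0.256 above the control mean (others −0.213 to −0.064, controls −0.275 to 0.23). In 4-HPAA replicate 5 Fasn was 38086 against 9088 to 17737 in the other 4-HPAA mice. In 4-HPAA replicate 2 Ugt2b37 was 157 and Ugt2b38 was 759, against at most 79 and 317 in the others of that group.

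Among controls, replicate 6 was low for Cpt1a, at 13178 against 16280 to 17006, and for the fatty acid oxidation score, at −0.515 against 0.019 to 0.175, and high for Ugt2b37, at 62, and Ugt2b38, at 185, against at most 20 and 61 in the other controls. Control replicate 5 was high for Cidea, at 636 against 14 to 170, and low for Ambp, at 46293 against 52130 to 54845, and for the hepatocyte marker score, at −0.163 against −0.019 to 0.062. Sh3pxd2a was 432 in control replicate 1 against 503 to 543 in the others. Nags was 1188 in control replicate 4, against 1449 to 1605, and 2223 in 4-HPAA replicate 3, against 1586 to 1739.

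4-HPAA replicate 3 stood apart from all libraries: its second component score was −56.45, its ribosomal protein score was 0.336 above the control mean (others of its group −0.114 to −0.015), and 1005 genes lay over 0.5 log2 below every other library, against 21 to 110 in the others. Its deviation rose with GC content across genes, with a rank correlation of 0.588 against at most 0.317 in size elsewhere, so a loss of low-GC transcripts in this library is a candidate cause (genes are not independent replicates). Removal of the GC trend left 438 such genes, against at most 104 in any other library, which argues against that trend, as measured here, as the whole cause. Of 4 Y-linked genes 3 lay below every other library, Ddx3y at 453 (others 1269 to 2092), Uty at 116 (249 to 459) and Eif2s3y at 939 (1372 to 1801), but Kdm5d was 457 (366 to 595), which argues against a mixture with female tissue, since that would lower all 4 alike. The deviation of this library also fell with transcript length, with a rank correlation of −0.309 against at most 0.171 in size elsewhere. Whether this is separate from the GC trend was not tested. No biological explanation was tested, and what else sets this library apart stays open.

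Acute phase genes were higher in 4-HPAA livers, most in replicates 1, 2 and 5, though the list did not pass with an estimated correlation (limma camera, adjusted p = 0.509). A GC trend between libraries is argued against, since the difference of the list's mean per mouse was 0.718 after removal of the trend, as before. A shift of all genes by a few abundant ones is argued against too: the median difference over all genes was −0.001 as deposited, against 0.548 for this list. Scaled to equal library totals the list's median was 0.518. That scaling moves all genes nearly alike, by about −0.03 in the median, so it adds no separate evidence. A response to 4-HPAA may account for the difference, as a hypothesis, but an unrelated inflammation in some of the 4-HPAA mice was not tested and stays open.

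Matrix genes and stellate cell markers fell together, though neither list passed with an estimated correlation (limma camera, adjusted p = 0.509 for each). Whether fewer stellate cells or lower expression per cell could account for this was examined with the 13 stellate cell markers outside the matrix list. All 13 had negative differences, but unevenly, from −0.05 ± 0.22 in Hand2 and −0.10 ± 0.33 in Lrat to −0.65 ± 0.14 in Reln (SE). Their mean per mouse differed by −0.368 ± 0.18 (SE), within 1 SE of the −0.491 ± 0.14 of the matrix list, as a smaller share of these cells would give. A smaller share alone would lower all 13 alike, which these single values are too uncertain to decide. Lower expression in an unchanged number of cells cannot be told apart from a smaller share, because either would lower these markers in whole liver. The difference of these markers had an exact permutation p of 0.0693. A GC trend between libraries is argued against by a matrix difference of −0.497 after its removal. A response of the cells to 4-HPAA stays open in both readings.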

How the results depend on the processing

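The alternatives named as added below, and the test of change in either direction, were chosen only after the data were seen. Under limma, 0 genes passed also with other scalings (that to equal library totals added) and filters. The same held with other pseudocounts (added) and with GC trends removed (added). The count was 7 with quality weights, 11 with the replicate block, 4 at an adjusted p under 0.1, 139 with array weights (added), 71 with the first residual component as a covariate (added) and 27 with GC trends removed and the replicate block (added). All 7 genes of the quality-weighted fit were among those of array weights. Leaving out 1 library gave 0 to 193 genes, with 193 without 4-HPAA replicate 4 and 5 without control replicate 1, and 0 otherwise. With GC trends removed and 4-HPAA replicate 3 left out (added) it was 0. The causes were not tested. Same-numbered mice were not taken as paired, since their correlations were mixed (−0.183 to 0.282), although 3 of 6 controls correlated best with their own number. The block gave 17 lists.

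The 18 lists became 0 with an estimated correlation, 0 with fry and 0 with exact permutation per mouse (added), where 3, 7 and 10 had an unadjusted p under 0.05. Each of these allows for genes that vary together. Exact permutation could hardly pass a list, however. Its smallest possible p, 0.00216, becomes 0.0779 after adjustment when only 1 of the 36 lists reaches it, as the acute phase list did. The 0 of that test therefore says little. The test of change in either direction (added) gave 14, and 1 to 21 with 1 library left out. The remaining settings gave 15 to 19 lists, and leaving out 1 library gave 15 to 20. Acute phase, matrix, stellate, lipid droplet, oxidation and cholesterol lists passed in 23 of 26 settings each, all but those 3. Hepatocyte markers passed in 12 and urea cycle genes in 15. Oxidative phosphorylation passed in 7, among them without 4-HPAA replicate 3, and macrophage markers in 4.

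Of 104 named genes, 2 changed sign. Fasn was at 0.086 with quality weights and 0.079 with array weights. Pck1 was at 0.05 with GC trends removed and 4-HPAA replicate 3 left out, and between −0.138 and 0.089 with 1 library left out. For AMPK and mTORC1 genes, not past the threshold in any setting, the direction of the camera test turned with the first residual component, though the median stayed at −0.015, with GC trends removed and replicate 3 left out, at 0.014, and without control replicate 2 or 3 or 4-HPAA replicate 3, the median ranging from −0.031 to 0.028 with 1 library left out. DESeq2 and svaseq were not run, as both need raw counts. The deposited values start at 2, so silent genes cannot be judged.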

Other observations

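The correlations, the fry test of change in either direction and the tests against other splits in this part were chosen only after the results were seen. Among zonation genes, the periportal list changed in either direction (21 genes, limma fry, adjusted p = 0.00186) but not on balance (limma camera, adjusted p = 0.549), and did so with each library left out (limma fry, adjusted p 2.62e-06 to 0.0219), with 3 higher and 3 lower genes when adjusted over the list alone and none over all genes. Hsd17b13 (−0.51 ± 0.10) and Alb (−0.38 ± 0.10) stood on the lower side, and Cyp2f2 (0.35 ± 0.08) on the higher. Pericentral genes did not pass (limma camera, adjusted p = 0.106), but passed as higher without control replicate 1 (adjusted p = 0.0091) or 4-HPAA replicate 2 (0.0391), within 0.0091 to 0.766 over 26 alternatives, the highest being the value with an estimated correlation.

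Other lists that did not pass limma camera were autophagy and lysosome genes (adjusted p = 0.634), interferon response and antigen presentation (0.634), T, NK and B cell markers (0.634), clock genes (0.635), ribosomal proteins (0.635), blood cell markers (0.326) and immediate early genes (0.84), whose median of −0.02 and mean of 0.00 differ in sign. Of these, blood cell markers passed in 2 of 25 alternatives, among them without 4-HPAA replicate 3 (limma camera, adjusted p = 0.0489), within 0.0403 to 0.843, the highest being the value with an estimated correlation. Ribosomal proteins passed in 3 of 26 alternatives, and had an adjusted p = 0.938 with an estimated correlation (limma camera). Neutrophil markers had 3 of 15 genes in the table (S100a9, Csf3r and Lcn2), exocrine pancreas 1 of 15 and mitochondrially encoded transcripts 0 of 13, too few to test.

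Chance was examined with 100 of the 462 splits of the 12 livers into 6 and 6, the real one included. For the count of genes the splits decide nothing, since all 100 must give at least the real 0. The highest other gave 16, and 129 with GC trends removed, where the real count was also 0. Chance cannot be excluded for the 1886 genes at an unadjusted p under 0.05, where 7 splits gave as many and the highest other gave 2319. Nor can it be excluded for the 18 lists of limma camera, where 9 splits gave as many and the highest other gave 22. The lowest other split gave 0 lists, and each of the rest gave at least 3. Camera at the preset correlation thus called lists in nearly every split, whatever the grouping, so its adjusted p-values alone are weak evidence. For lists changed in either direction (limma fry), the real 14 was reached in 4 splits, with 20 in the highest other, a share under 0.05. It is the smallest share of 5 counts, the count was taken up after its p-values had been seen, and it was 1 to 21 with 1 library left out, so chance is not taken as excluded. The split that called 129 genes may point to a structure of the samples, for which no test was run.

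As a hypothesis, mice of each group may vary along the axis that separates the groups. Over the 6 control mice the lipid droplet score ran against the growth hormone score, with Pearson r of −0.879 (exact permutation, p = 0.0125; 0.025 after Benjamini-Hochberg adjustment over 4 relations) and Spearman rho of −0.943 (exact permutation, p = 0.0167; adjusted 0.0334). Over the 6 4-HPAA mice r was −0.985 (exact permutation, p = 0.00278; adjusted 0.0111) and rho was −0.943 (p = 0.0167; adjusted 0.0334, exact permutation). Without the 2 mice farthest from the median lipid droplet score, r was −0.942 and −0.88. For the acute phase score 6 mice per group do not decide: r was 0.554 in controls (exact permutation, p = 0.249; rho 0.143, p = 0.803) and −0.675 in 4-HPAA mice (exact permutation, p = 0.161; rho −0.771, p = 0.103), and 0.528 and −0.719 without the 2 farthest mice. In controls as in 4-HPAA mice, a lower lipid droplet score thus went with a higher score of growth hormone-dependent and sex-biased genes. Members of the latter list differed between the groups in both directions, 22 higher and 9 lower, so its score is a mixed one. Adjustment over 4 relations leaves out the other pairs of lists that could have been chosen. The design cannot say which score leads.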
